A study of Mus musculus with 3 samples.

How the data were processed

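ChIP-seq peak lists of mouse skeletal muscle were analysed: GR ChIP in GR(i)skm-/- muscle and H3K27me3 ChIP in WT muscle, each from 1 library. Per the labels, the authors called bases with bcl2fastq 2.17.1.14, aligned reads with Bowtie 1.0.0 to mm10 and called peaks with MACS2, whose version is not given. The control used for calling and the treatment of reads with several matches are not stated. The deposited score column is 10 times the -log10 q, in whole numbers. The deposited ratio is MACS2's fold enrichment over the local background, with 1 read added to both. The deposited -log10 p and -log10 q are MACS2's own, and every -log10 q in the GR list is at least 20. Peak numbers in that list run to 12933 with 9846 missing, so it had been filtered to 23.9% of the numbered peaks, while the H3K27me3 list goes below a -log10 q of 20 in 198 regions. Neither list gives a read total.

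For each GR peak the whole number of reads at the summit was recovered from fold enrichment and -log10 p under the Poisson model of MACS2. All 3087 were solved within 0.001, with 12 to 92 reads and a median of 17, and 1209 peaks (39.2%) rested on 12 to 15 reads. The background was under 0.07 reads in 1844 peaks (59.7%).

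Regions were placed on GRCm38 with GENCODE vM21 genes, and tRNA and 5S rRNA genes from the RefSeq annotation. Peaks were placed by their summit, and H3K27me3 regions by their midpoint. Promoters were within 1000 bp of a protein-coding start site. A gene counted as marked when any part of a peak or region lay within that distance. Each list was compared with 10000 random placements on its own chromosomes outside gaps, or 100 where sequence was read, giving two-sided permutation p-values of at least 0.0002. Benjamini-Hochberg adjustment was applied within each family of tests. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only.

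Tandem repeats were perfect tracts of units of 1 to 6 bp, at least 3 units and 8 bp long, and a region counted as one when they covered 50% of its bases. With 80% in place of 50% the share of GR peaks was 49.98%. LINE-1 was called by blastn 2.17.0 at 50% coverage against 300 of 3508 open reading frames of at least 1200 codons with a reverse transcriptase motif, extended by 1300 bp before and 600 bp after. The ribosomal RNA repeat was called by similarity to a reference stretch, and satellite-like arrays by similarity to arrays on chromosomes 9 and 2. Sequence in and around a region also counted as satellite-like at 70% identity to itself at a shift of 50 to 400 bp. Regions of both lists lie inside these reference arrays, so the share of satellite-like regions partly follows from that choice. Random windows for these classes came from 5 placements of the GR list and 20 of the H3K27me3 list. The number of genome positions of each 31-mer was counted in both strands.

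Two-sided Fisher's exact tests compared 16 gene lists fixed before the data were examined, for both peak lists: glucocorticoid-induced, contractile and calcium handling, muscle energy, myogenic, Hox, developmental, signalling, neuronal, ribosomal protein and histone genes, and endothelial, fibroblast, leukocyte, satellite cell, adipocyte and smooth muscle, and liver and germline genes. An exact McNemar test compared 17 fixed motifs in 200 bp windows with windows 1000 bp away. The genes named were fixed by rule: the 20 regions of highest fold enrichment per list with the nearest start site, every list member with a region within 1000 bp, up to 8 per list, and Fkbp5, Per1, Tsc22d3, Nr3c1, Myod1, Acta1, Ckm, Trim63 and Fbxo32. Chromosome counts were tested with two-sided exact binomial tests against length. The sequence classes, tract counts, tRNA genes and chromosome values per tract were chosen after the data were examined.

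Alternatives covered other promoter windows, stronger peaks, peaks outside soft-masked sequence, other placements and overlap rules, other gene windows and a background matched by CpG class, other motif windows, and covered length in place of counts. On simulated data, 7 of 200 lists of random positions gave p under 0.05. All 200 lists with 3% of positions moved to start sites did. All 1000 simulated pileups and all 1000 planted repeats were recovered, and 0 of 1000 random windows were called as repeats. The pileups were simulated with the formulas used to recover them, and the planted repeats met the calling rule. Their recovery therefore checks the code only. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, Biopython 1.88 and matplotlib 3.10.9 were used. No expression test was run, since the lists hold no counts.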

Results

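Chromatin immunoprecipitation with sequencing was applied to nuclei of skeletal muscle from C57/Bl6J mice aged 10 to 12 weeks. The GR list came from muscle of GR(i)skm-/- mice, titled as knockout for the glucocorticoid receptor (GR, the hormone-activated transcription factor encoded by Nr3c1), with an antibody to the receptor's C terminus. It held 3087 peaks with a median width of 68 bp. The H3K27me3 list came from wild-type (WT) muscle and held 399 called regions with a median width of 255 bp. H3K27me3 is the histone mark that Polycomb complexes place on silenced genes. A place in the list does not show that a region carries the mark. Each group had 1 library and no replicate, so every value describes a single library and every test compares a list with random positions or other genes. The input library of GR(i)skm-/- muscle had no peak list and was not analysed here, and no GR ChIP of WT muscle was among the samples given. Total reads per library are unknown. The fold enrichments and their p-values are the authors' own and were compared only within a list. The fold adds 1 read to peak and background, so in the GR list, with a median background of 0.065 reads, it mostly follows the reads at the summit.

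The listed GR peaks of GR(i)skm-/- muscle lay mostly on simple repeats. The list had been filtered to 23.9% of the numbered peaks, and the peaks left out cannot be seen. Of the 3087 peaks, 2654 (86.0%, exact 95% interval 84.7 to 87.2%) lay in tandem repeats of 1 to 6 bp units, against 1.43% of randomly placed windows of the same widths. The share was 49.98% where repeats had to cover 80% of a peak's bases in place of 50%. Fkbp5, a receptor co-chaperone, and Tsc22d3, the anti-inflammatory leucine zipper protein, had no peak within 1000 bp of a start site or in the gene body. The same held for Per1, a circadian repressor, for Trim63 and Fbxo32, the muscle atrophy ubiquitin ligases, and for Nr3c1 itself. Weaker peaks at these genes could have been removed by the filter. The repeats were mainly GA tracts, the dominant unit of 1453 peaks (54.8% of those in tandem repeats), and CA tracts, of 591 peaks (22.3%).

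The strongest peak lay 665 bp from the start site of Trim29, a tripartite motif protein, on chromosome 9 from 43310114 to 43310228, in a GA repeat, with a fold enrichment of 74.7 and 81 reads at its summit. Peaks in introns of Agbl1, a carboxypeptidase of the cytosol, and Akirin2, a nuclear adaptor protein, reached 74.2-fold and 69.5-fold. The peaks nearest to Spcs3, a signal peptidase subunit, to Nova1, a neuronal splicing factor, to Rasgrf2, an exchange factor for Ras, and to Cst10 reached 70.4, 68.5, 68.5 and 68.1-fold. The next 3, nearest to Fgd6, Cacna2d1, a calcium channel subunit, and Maneal, reached 66.7, 66.7 and 64.9-fold. The rest of the 20 strongest, at 57.9 to 64.6-fold, were nearest to Pcdh20, Scel, Wnt5a, a secreted signalling protein, Fscb, Adcy1, an adenylate cyclase, Plxna4, a semaphorin receptor, Rybp, a Polycomb subunit, Tcf4, Ntrk3, a neurotrophin receptor, and Srek1. Tandem repeats held 17 of these 20 peaks, 11 of them GA repeats, and 3 of the 20 lay within 10 kb of a start site. Peak strength rose with width across peaks, which are not independent replicates (Spearman's rho 0.339, Pearson's r 0.217, two-sided permutation p of rho = 0.0001, the smallest that 10000 permutations can give).

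The nearest peaks to the 9 genes fixed in advance lay 10.4 to 905.6 kb from a start site. For Fkbp5, Tsc22d3, Nr3c1 and Trim63 they lay 512.3, 155.9, 451.4 and 293.1 kb from a start site, each in a GA repeat. For Fbxo32, for Myod1, the myogenic master regulator, and for Ckm, the muscle creatine kinase, the distances were 905.6, 352.1 and 91.9 kb. For Acta1, the skeletal muscle actin, the nearest peak was a telomere-type repeat 66.8 kb away, with a fold enrichment of 27.5. For Per1 it was a serine tRNA gene 10.4 kb away, n-TScga3, with a fold enrichment of 16.8.

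**Figure D1:**
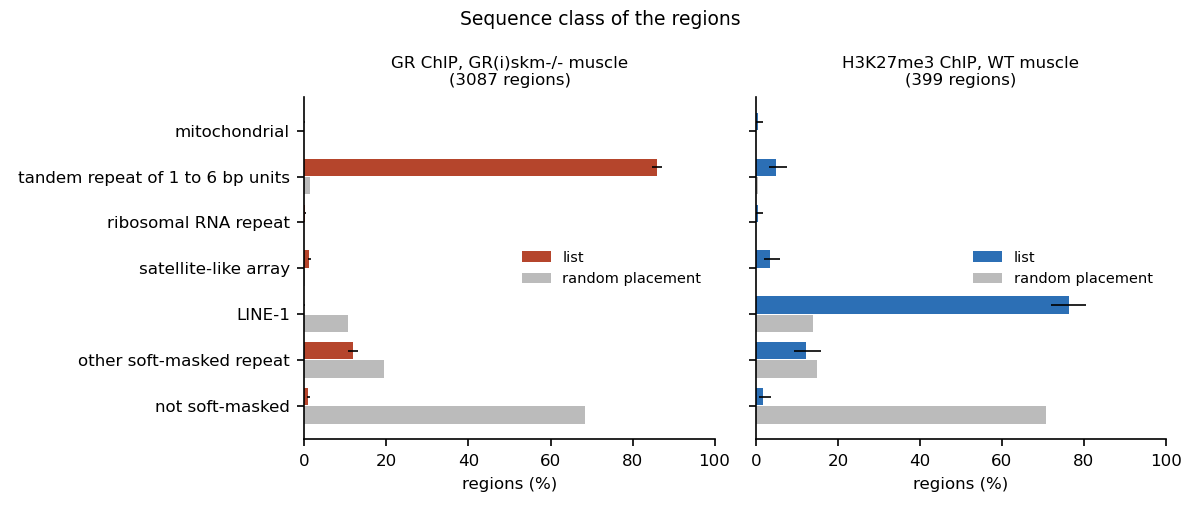
Share of regions in each sequence class (horizontal axis, percent) for the GR ChIP list of GR(i)skm-/- muscle and the H3K27me3 list of WT muscle, with exact 95% intervals, beside random placement (grey). Tandem repeats hold 86.0% of the GR peaks (49.98% where they must cover 80% of a peak) and LINE-1 elements hold 76.4% of the H3K27me3 regions.

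Not every repeat carried peaks. Of the 125128 GA tracts of at least 20 bp in the genome, 1.28% overlapped a peak, and of the 279755 CA tracts 0.365% did. TA tracts carried none: 0 of 14655 tracts of 20 to 29 bp overlapped a peak, and none of the longer ones did. Of the 589 telomere-type tracts of unit AACCCT, the sequence of chromosome ends, 110 (18.7%) overlapped a peak. Only 34 peaks in tandem repeats had this dominant unit, so several of these tracts could share a peak. Counted by tract, overlap with a peak was most frequent for the shortest GA tracts, at 2.15% of those of 20 to 29 bp (exact 95% interval 1.99 to 2.32%) against 0.651% of those of 60 bp and more (0.529 to 0.793%). For CA tracts the share was 0.622% at 20 to 29 bp and 0.189% at 40 to 59 bp, and 0.411% for the 15 of 3650 tracts of 60 bp and more. Only perfect tracts were counted, so an interrupted repeat gave several tracts that a single peak could cover. The intervals treat such tracts as independent, and a preference of peaks for short repeats is not shown. LINE-1 elements, the most abundant mobile elements of the mouse genome, held 0 of the 3087 peaks against 10.7% of random windows.

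**Figure D2:**
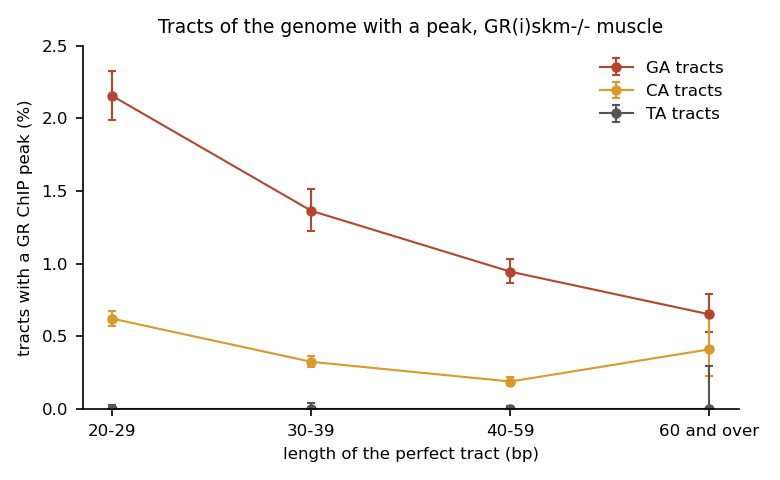
Percent of perfect GA, CA and TA tracts of the genome that overlap a GR ChIP peak of GR(i)skm-/- muscle (vertical axis), by tract length in bp (horizontal axis), with exact 95% intervals. GA tracts go from 2.15% at the shortest length class to 0.651% at the longest, and TA tracts stay at 0. Tracts that share a peak are counted separately.

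Promoters of protein-coding genes held 70 peaks (2.27%, exact 95% interval 1.77 to 2.86%), against 64.6 at random positions (two-sided permutation p = 0.525). Placing all peaks on tandem tracts, chosen after the data were seen, gave 47.8 (ratio 1.46, permutation p = 0.0014), but does not suit the peaks of other classes. Of the 2654 peaks in tandem repeats, 41 lay in promoters, against 44.8 with random positions on tracts of the same unit (permutation p = 0.634), a comparison chosen after the data were seen. Among their genes were Il1b, which encodes interleukin 1 beta (peak at 123 bp, 20.7-fold), Trib3, a pseudokinase of stress signalling (25.1-fold), Fxyd1, the muscle sodium pump regulator phospholemman (19.4-fold), and Foxp2 (13.1-fold), all 4 in GA repeats and named after their values were seen. Coding exons held 3 peaks against 37.5 at random (permutation p = 0.0002, the smallest that the 10000 placements can give, adjusted p = 0.0008), and untranslated regions 19 against 40.96 (adjusted p = 0.0024). Introns held 1282, against 1283 at random. The random positions for exons, untranslated regions and introns were not limited to repeat tracts. Without the peaks over 50% soft-masked, 5 of the remaining 41 lay at promoters against 0.971 at random (permutation p = 0.0046). Of the 5, 3 lay on tRNA genes, and without the tRNA peaks 2 of 28 lay at promoters against 0.649 (permutation p = 0.279).

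The gene lists fixed in advance held a single marked gene. Hist1h4a, a core histone gene on chromosome 13, had a peak 147 bp from its start site, from 23761054 to 23761104, with a fold enrichment of 12.6, and was the only marked member of the 37 canonical histone genes (two-sided Fisher's exact p = 0.0969, adjusted p = 1 over 32 list tests). No promoter peak fell on the 40 glucocorticoid-induced genes, the 40 contractile and calcium handling genes, the 31 muscle energy genes or the 18 myogenic regulators. None fell on the 39 Hox genes, the 125 developmental factors, the 53 signalling genes, the 44 neuronal genes or the 52 ribosomal protein genes. The markers of other cell types held none either, with 20 endothelial, 20 fibroblast, 22 leukocyte, 15 satellite cell, 18 adipocyte and smooth muscle, and 21 liver and germline genes. In all, 60 of 21827 genes were marked, so a list of 40 held 0.110 marked genes on average and an absence there carries little weight. With windows of 5000 bp, 4 of the 37 histone genes were marked against 0.449 by the background (Fisher's exact adjusted p = 0.0328), but all 4, Hist1h1a, Hist1h3a, Hist1h4a and Hist1h4b, by the same 1 peak, so the test has no independent genes behind it. With gene bodies and 5000 bp upstream, 2 histone genes were marked against 1.80 expected (Fisher's exact p = 0.701), and 2 of the 40 glucocorticoid-induced genes against 1.95 (Fisher's exact p = 0.722). The lowest p in that setting was that of the neuronal genes, with 6 of 44 against 2.14 (Fisher's exact p = 0.0191, adjusted p = 0.611). Gene length was not matched.

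The glucocorticoid response element, the receptor's binding sequence, was not more frequent in peaks. It occurred in 5 of 3087 central windows of 200 bp and in 11 windows 1000 bp away (exact McNemar p = 0.210, adjusted p = 0.275 over 17 motifs). Of the other motifs only the CA run was more frequent in the centre at an adjusted p under 0.05, in 1123 peaks (36.4%) against 101 flanks (3.27%). Most other motifs were rarer in the centre: CAGCTG, the E-box of myogenic factors, was in 50 centres and 228 flanks (exact McNemar adjusted p = 1.6e-28), and the MEF2 site in 1 and 15 (exact McNemar adjusted p = 2.6e-04). In all, 10 motifs were rarer in the centre at an adjusted p under 0.05. Only 4 were in the 433 peaks with under 50% of their bases in tandem tracts. With so many fewer peaks the tests had less reach, so the lower count does not show a change. These 433 peaks were not free of repeats, since the CA run was in 73 centres (16.9%) and 6 flanks (1.39%). There CAGCTG stayed rarer, in 6 centres and 29 flanks (exact McNemar adjusted p = 3.8e-04), while the MEF2 site was in 0 and 1 and the response element in 1 and 0 (exact McNemar p = 1 for both). The looser core of the element, ACANNNTGT, was rarer in the centre in all peaks (83 against 201, exact McNemar adjusted p = 2.4e-12) and in these 433 peaks (11 against 27, exact McNemar adjusted p = 0.0385). With 1 mismatch allowed, the response element was rarer in the centre too, in 74 peaks against 238 flanks (exact McNemar p = 4.1e-22). The CCAAT box was likewise in 271 centres and 832 flanks. Most centres lay in tandem repeats, which leave less room for other motifs than the flanks do. Rarity in the centre therefore cannot be read as a trait of the response element, the E-box or the MEF2 site.

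The H3K27me3 list of WT muscle lay mainly on LINE-1 elements. LINE-1 elements held 305 of 399 regions (76.4%, exact 95% interval 72.0 to 80.5%), against 13.95% of random windows. None of the 39 Hox genes, which pattern the body axis, of the 125 developmental transcription factors such as Pax6, Sox2 and Gata4, or of the 53 Wnt, BMP, FGF and Hedgehog genes had a region within 1000 bp of a start site. Fold enrichments of the LINE-1 regions had a median of 13.9. Satellite-like arrays held a further 14 regions (3.51% against 0.025% at random), and the mitochondrial genome held 2 that covered 39.1% and 32.7% of its 16299 bp at 2.74-fold and 3.08-fold.

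All 20 strongest regions were LINE-1 sequence, 267 to 278 bp wide and 30.3 to 39.5-fold enriched. The strongest lay on chromosome X from 124111491 to 124111765, 24.3 kb from Vmn2r121, a vomeronasal receptor, at 39.5-fold. The next lay 459.7 kb from Brinp1 at 38.3-fold, in an intron of Btbd8 at 35.4-fold and 21.8 kb from Mllt3, a reader of acylated histones, at 35.3-fold. Those nearest to Cntnap5b, Gm10283, Spinkl, Sybu, 2610301B20Rik and Tdrd3 reached 33.3, 33.2, 33.2, 32.7, 32.7 and 32.6-fold. The remaining 10 were nearest to Zfp946, Rundc3b, Ndufa4, which had 2 regions, Rpia, Zfp990, Cenpq, Olfr159, Pax1 and Prim2. The Pax1 region lay 230.2 kb from its start site. Across the list strength rose with width by rank (Spearman's rho 0.522, two-sided permutation p = 0.0001, the smallest that 10000 permutations can give) but not on the original scale (Pearson's r = -0.134).

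The LINE-1 regions were closer to intact elements than random LINE-1 windows. Their median identity to a library of intact second reading frames, the part that encodes the reverse transcriptase, with the sequence around them, was 94.0% against 89.8% for random LINE-1 windows, and 137 of 305 (44.9%) reached 95% identity against 27.4%. Fewer of the regions than of the random windows lay before the reading frame, 44 of 305 (14.4 against 27.9%). Within classes of place, a test chosen after the data were seen, they had the higher identity in 68.2% of pairs (permutation p = 0.0002, the smallest possible), though the medians were close after the reading frame (92.2 and 92.0%) and in its first part (92.4 and 91.9%). By chromosome, the number of LINE-1 regions per Mb rose with the number of intact reading frames per Mb over the 21 chromosomes (Spearman's rho 0.764, permutation p = 0.0002, and Pearson's r 0.731, permutation p = 0.00013). Without X and Y, the chromosomes farthest from the median, r was 0.729 and rho 0.709. Chromosome 11 had fewer regions of any class than its length gives, 5 against 17.8 (ratio 0.281, exact binomial adjusted p = 0.0083).

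**Figure D3:**
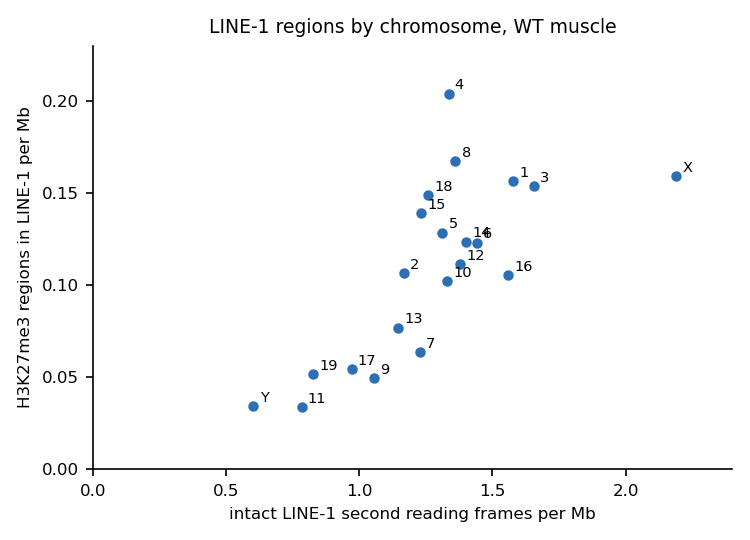
H3K27me3 regions in LINE-1 elements per Mb (vertical axis) against intact LINE-1 second reading frames per Mb (horizontal axis), 1 point per chromosome, in WT muscle. The values go from 0.0337 on chromosome 11 to 0.204 on chromosome 4, and Spearman's rho is 0.764.

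Promoters held 8 of the 397 nuclear regions (2.02%, exact 95% interval 0.874 to 3.93%), against 7.64 at random (two-sided permutation p = 0.982). The genes with any part of a region within 1000 bp of a start site, wherever its midpoint lay, were 7 predicted genes inside satellite arrays and Stau2. The predicted genes were Gm10717, Gm10718, Gm10722, Gm10800, Gm10801, Gm11168 and Gm17535. Stau2, an RNA transport protein, had its region in a GA repeat at 7.49-fold, and all were named after their values were seen. Intergenic sequence held 279 regions against 212.1 at random, and introns 107 against 160.8 (permutation p = 0.0002 for both, the smallest possible, adjusted p = 0.0008). The random positions were not limited to LINE-1 sequence. Of the 9 fixed genes, Ckm had the nearest region, 1150 kb away, and Trim63 the farthest, 11160 kb away. None of the 16 gene lists had a marked member, and only 8 of 21827 genes were marked, so the list tests had little reach. Within 5000 bp of start sites there were fewer regions than at random, at a ratio of 0.479 (permutation p = 4.0e-04).

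The lists overlapped mainly at satellite arrays. Of the GR peaks, 19 (0.616%, exact 95% interval 0.371 to 0.960%) overlapped an H3K27me3 region, against 0.178 at random positions (two-sided permutation p = 0.0002, the smallest that 10000 placements can give). Satellite-like arrays held 12 of the 19, tandem repeats 4, the ribosomal RNA repeat 2 and sequence that is not soft-masked 1. On chromosome 9, 4 of them lay in the major satellite-like array between 3000374 and 3023565, with fold enrichments of 12.1 to 18.8. On chromosome 2, 5 lay in the array between 98662250 and 98667302, at the predicted genes Gm10800 and Gm10801, at 12.5 to 23.3-fold. The H3K27me3 regions that these peaks overlapped reached only 8.20-fold on chromosome 9 and 3.57-fold on chromosome 2, below their list's median of 11.8. Among the peaks and regions stronger than the median of their list, which leaves out these arrays, 1 overlap remained against 0.043 at random (permutation p = 0.085).

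Both sex chromosomes carried few GR peaks for their length. Chromosome X had 101 peaks against 190.6 (ratio 0.530, two-sided exact binomial adjusted p = 8.6e-12) and chromosome Y had 30 against 102.8 (ratio 0.292, adjusted p = 9.7e-16). The deficit was also present per repeat: of the GA tracts of at least 20 bp, 0.930% on X and 0.486% on Y overlapped a peak, against 1.03 to 1.85% on the 19 autosomes (Fisher's exact p = 0.0044 and 1.4e-08). For CA tracts the values were 0.131% on X and 0.0299% on Y, against 0.293 to 0.495% (Fisher's exact p = 4.4e-07 and 6.2e-09). None of these comparisons allowed for the number of copies of X and Y per cell, and tracts that share a peak were counted separately. The cause of the low counts was not tested. In the H3K27me3 list, X had 31 regions against 24.5 (exact binomial adjusted p = 0.489) and Y had 6 against 13.2 (exact binomial adjusted p = 0.202). The 2 lists come from different mice and antibodies, and the difference between them was not tested.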

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

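Some alternatives were chosen after the data were seen: placement on tandem tracts or soft-masked bases, and lists without repeat regions or without tRNA peaks. The limit of 80% for a repeat class and the values per tract on the sex chromosomes were too. So were the motifs in peaks with under 50% of their bases in tandem tracts. All others were chosen before. Of the 56 values under an alternative, 40 kept their direction and their side of the threshold or, for values with no test, their range. The gene list tests of H3K27me3 regions gave 4 of these 40 and could hardly change. Few genes were marked there, and 0 of 21827 with the stronger regions alone. The overlap of the lists was 9.43 to 181.3 times the random level under its 9 alternatives, on 1 peak against 0.0178 once repeat regions were left out (permutation p = 0.036). It missed the threshold only among the stronger regions of each list (ratio 23.04, permutation p = 0.085), also on 1 peak. That cut leaves out the weak H3K27me3 regions of the shared arrays on chromosomes 9 and 2. The low share of GR peaks on X stayed at 0.462 to 0.630 of the random level and that on Y at 0.214 to 0.372, where the values per tract set peaks on tracts of any length against tracts of at least 30 bp. The promoter share of GR peaks, at 1.08 times the random level, was 0.993 within 5000 bp, 0.804 among the stronger peaks, 1.46 against placement of all peaks on tandem tracts (permutation p = 0.0014), which does not suit the peaks of other classes, 0.916 for tandem repeat peaks alone on tracts of their own unit (permutation p = 0.634) and 5.15 outside soft-masked sequence, where 41 peaks remained, or 3.08 without the tRNA peaks among them (permutation p = 0.279). The promoter share of H3K27me3 regions, at 1.05, was 0.560 within 2500 bp, 0.479 within 5000 bp, 0.917 by any overlap, 2.13 against placement on soft-masked bases (8 against 3.76, permutation p = 0.082), 0 of 200 among the stronger regions against 3.83 expected (permutation p = 0.0438, while the main p was 0.982), and 0 of 11 outside soft-masked sequence. With windows of 5000 bp, 1 gene list of the GR peaks passed, the histone genes, all by the same 1 peak, and 0 did in the other gene list alternatives. The odds of the glucocorticoid response element, with 0.5 added to both counts, were 0.478, then 0.0909 in windows of 50 bp on each side (0 centres, 5 flanks). They were 0.295 with 1 mismatch allowed. In the 433 peaks with under 50% of their bases in tandem tracts they were 3.00. That value rests on 1 centre and 0 flanks (exact McNemar p = 1) and shows no change. In the same peaks the count of rarer motifs went from 10 to 4, which the smaller number of peaks can give by itself. The share of GR peaks in tandem repeats was 49.98% with the limit at 80%, and that of H3K27me3 regions in LINE-1 was 74.7%. For all of these the cause was not tested. The weakest GR peaks rest on 12 reads, and what depth limits is unknown, since read totals are not given.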

Other observations

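The tests of tRNA genes, repeat copies, LINE-1 copies and distance to genes were chosen after the results were seen, and only the test of response elements beside repeat tracts was written before its result, when the element's low frequency in the peaks themselves was already known. GR ChIP peaks of GR(i)skm-/- muscle also lay on genes of RNA polymerase III, which makes tRNA and 5S rRNA. Peaks fell on 13 of 402 tRNA genes (3.23%, exact 95% interval 1.73 to 5.47%), against 0.083 at random positions (two-sided permutation p = 0.0002, the smallest possible), and made up 13 of the 29 peaks outside soft-masked sequence and the named repeats. The strongest were n-TStga3, a serine tRNA gene on chromosome 10 from 63429476 to 63429557 (33.5-fold, in the promoter of Ctnna3), the isoleucine gene n-TIaat3 (28.4-fold) and the aspartate gene n-TDgtc16 (26.96-fold). Of the 54 5S rRNA genes, n-R5s211, n-R5s194, n-R5s115 and n-R5s2 had a peak, 4 against 0.011 at random (permutation p = 0.0002). The H3K27me3 list had 0 regions on either. The peaks on n-TLaag4 and n-TAagc9 lay in the promoters of Polr3e, which encodes a subunit of RNA polymerase III (14.2-fold), and of Ppp6r3 (21.4-fold). The ribosomal RNA repeat, at 39846745 to 39848231 on chromosome 17, held 5 peaks of 10.7 to 19.5-fold.

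For the tRNA peaks, placement of reads shared between identical gene copies is argued against by the annotation: genes with a peak had more identical copies than genes without one in only 23.2% of pairs (permutation p = 0.0002, the smallest possible), and 12 of the 13 were unique in sequence. Reads shared between similar tRNA genes stay open, since 7 of the 13 peaks had 2 to 6 genome positions per 31-mer, although genes with a peak had more positions in only 32.5% of pairs (permutation p = 0.0282). The peaks kept to the genes, with 19 bp in all beyond the gene ends against 391.6 bp with random offsets (permutation p = 0.0002, the smallest possible). Whether the fragments were as short as the tRNA cannot be told, since tRNA peaks were wider than other peaks in 37.6% of pairs (permutation p = 0.128) and both had a median width of 68 bp. No biological explanation was tested, since the list has no WT counterpart here.

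For the peaks on GA and CA tracts, receptor that remained in the tissue could have bound response elements beside the tracts, but such elements were not more frequent there. Elements with 1 mismatch allowed lay within 100 bp of the ends of 92 of 2624 tracts with a peak, 0.679 times the number at tracts of the same unit and length class without one (exact conditional p = 3.3e-05), and 0.634 times in windows centred on the tract. The tracts were not matched by the sequence beside them, and tracts that share a peak were counted separately. The comparison therefore cannot decide the explanation. Whether reads that match many positions gathered at the most repeated tracts cannot be told: within classes of tract length, tracts with a peak had more genome positions in 52.3% of pairs for GA and 60.5% for CA (permutation p = 0.0248 and 0.0002), but fold enrichment fell slightly with the positions of the peaks' own 31-mers, whose median was 12 (Spearman's rho -0.051, Pearson's r of logarithms -0.0734, permutation p of rho = 0.0242). Without regard to length the order was the reverse, 41.3 and 46.3%, as tracts with a peak were shorter, while unique windows were rarer at tracts with a peak (3.80 against 7.70% for GA and 3.63 against 14.2% for CA). Receptor binding without a response element, antibody cross-reaction and preferred amplification of such DNA were not tested, nor was any biological explanation.

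For the H3K27me3 list, which lay mainly on LINE-1, few regions lay near genes: 16 of 397 were within 5000 bp of a protein-coding start site (4.03%), with an exact 95% upper limit of 6.46%. Most of the list was thus not at the start sites of Polycomb-covered genes. The limit of 5000 bp was chosen when the place of the regions was known, so this describes the list and is not a test. None of the 217 members of the Hox, developmental and signalling lists had a region within 5000 bp of a start site, which carries little weight since 0.169 were expected. Fold enrichment rose with the number of genome positions per 31-mer across the 305 LINE-1 regions (Spearman's rho 0.239, Pearson's r of logarithms 0.271, permutation p of rho = 0.0001, the smallest possible), from a median of 11.3 in the least repeated of 3 classes to 17.1 in the most repeated. Reads from a large family of near-identical copies, collected at some of them, may therefore have formed these regions. H3K27me3 on young LINE-1 elements stays open, since enrichment also rose with identity to intact elements (rho 0.193, permutation p = 6.0e-04), and no link between identity and positions was found (rho 0.0877, permutation p = 0.129).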
